A study of Mus musculus with 9 samples.

How the data were processed

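Gene expression was measured in mouse bone-marrow-derived mast cells on 9 Illumina mouse Ref-8 beadchips, single-colour arrays on which biotin-labelled RNA binds beads that carry probe sequences. Mast cells are tissue immune cells that release histamine and proteases when the IgE receptor on their surface is cross-linked. The cultures came from control C57BL/6J mice, from AhR null mice and from AhR-d mice, with 3 arrays per genotype. AhR, the aryl hydrocarbon receptor, is a ligand-activated transcription factor. Marrow was cultured for 4 weeks in medium with 30% supernatant of WEHI-3 cells, an IL-3-secreting line, then purified with magnetic beads that remove other cells and rested for 4 h without cytokines, per the labels' protocols. The labels give each array a batch number, and each of the 3 batches held 1 array of every genotype. Replicates were therefore separate culture batches; whether each came from a different animal is not given in the sources used here, and p-values measure the spread between these cultures.

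The deposited table of all probes holds linear signal intensity for 25697 probes, with no scaling between arrays, and the submitters' processing notes name GenomeStudio as the software, with no version. Per the file headers, each intensity column is followed by its detection p-value, which the authors' software took from negative-control beads. A deposited series table holds log2 values. Set against the log2 of each array's signal, every column of it differed by 1 constant per array, which placed the array's median at 8, so no other normalisation or background removal had been applied; the constants ranged from 0.231 to 0.928. A further deposited table repeats the intensity of 45 probes chosen by the study, equal to the full table within 9e-04; its 9 detection p-value columns were not used. Nothing in these sources states a statistical test.

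From the intensities and detection p-values, background was modelled with normexp, an offset of 16 was added and arrays were quantile-normalised on the log2 scale (neqc in limma 3.58.1, R 4.3.3). A probe was kept if its detection p-value was under 0.01 on at least 3 of the 9 arrays, which left 9777 probes. The platform annotation gave 23978 probes 1 gene symbol, none several, and left 1719 unnamed. Entrez identifiers of 23962 probes matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; that table was used only for names and for which genes neighbour each other. For a gene with several probes, the probe with the highest mean value was used. The 7445 features tested comprised 6860 named genes and 585 unnamed probes, which were counted but not named.

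The 3 pairwise comparisons came from 1 limma fit with a mean per genotype over all 9 arrays, moderated variances with an intensity trend, 6 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Adjusted p-values in the text are from this fit, fold changes are log2 with their standard error (SE), and group levels are mean normalised log2 values ± SD over 3 arrays. A gene not detected on any array of a group has only a bound there. Its difference is given as at least N-fold, the brighter group's mean over the mean of the higher of its own value and the lowest detected signal on each array of the dimmer group. Array number limits the precision of every value.

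Lists of genes were fixed in advance and tested with camera at a preset correlation of 0.01, adjusted over all lists of a comparison. Camera with an estimated correlation, fry and counts of members past the threshold were computed beside it. Of 30 lists, 28 had at least 3 measured members; the eosinophil and lymphocyte lists had 1 measured gene each and were not tested. The adjustment ran over these 28 and the list of probes chosen by the study, 29 lists in all. The genes named were set by a rule written in advance. It took the 10 largest changes in each direction that passed the threshold with 1 sign in all 3 batches, up to 4 members with the smallest p from each list that was called or had a called member, and 10 fixed genes (Ahr, Arnt, Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Kit, Fcer1a, Hmox1). Named genes outside the rule are marked as chosen after their values were seen. Kit is not analysed here.

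Whether batch numbers pair the arrays was checked on deviations from the genotype means. All 9 pairs of arrays from 1 batch correlated between 0.11 and 0.36, and the 18 pairs from different batches between -0.36 and 0.067. With the labels' statement of shared batches, the numbers pair the samples, and a fit with batch as a block was computed beside each result. Calls named in the text, and calls lost with an array left out, are from fits without the block unless stated. The spread in those fits includes differences between batches.

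Other settings, chosen before the data were examined like the lists and rules here, were the deposited log2 values, median scaling, no background correction, no filter or a stricter one, every probe, other variance settings, array weights, only the 2 groups compared, batch as a random block and each array left out in turn. Added after seeing the data were scaling on detected probes, cyclic loess, covariates for array brightness and for neutrophil transcripts, and a run without batch 3. The neutrophil covariate was each array's mean over the neutrophil list, which was itself higher in both altered genotypes. It therefore overlaps with genotype, and a call lost with it cannot tell a myeloid source from lost precision. The fit was tested on simulated data of 7445 genes for AhR null against control. It recovered 98.5% of the 66 genes changed 4-fold, 47.8% of the 67 changed 2-fold and 7.46% of the 67 changed 1.5-fold, with 7 false calls among 109. In a simulated list test, a list shifted by 0.5 log2 units was called and 0 other lists were. Figures were drawn with matplotlib 3.10.9.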

Results

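The data comprise 9 arrays of purified, resting bone-marrow-derived mast cells, with 3 control, 3 AhR-d and 3 AhR null arrays. The AhR null genotype lacks a functional receptor. The d allele of Ahr is known for encoding a receptor that binds ligands less tightly than the allele of C57BL/6J mice. The number of probes detected ranged from 7901 on AhR-d replicate 3 to 9733 on AhR null replicate 2. Mean raw signal was 404 ± 108 in control, 493 ± 176 in AhR-d and 588 ± 58.5 in AhR null arrays (SD, n = 3). By geometric mean AhR null arrays were 1.48 times as bright as controls, with an exact two-sided permutation p of 0.2, where 0.1 is the smallest this design allows. Normalised arrays of 1 genotype correlated at 0.946 to 0.978 across genes, and arrays of different genotypes at 0.885 to 0.966.

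The genotype labels could not be checked on Ahr itself. Its only probe was not detected on any of the 9 arrays, controls included, and its detection p-values ran from 0.115 to 0.833. Cyp1a1, the classical AhR-induced monooxygenase, was likewise not detected on any array. Arnt, which encodes the dimerisation partner of AhR, was detected on 4 of 9 arrays, with a log2 difference of -0.43 (SE 0.37, adjusted p = 0.477) in AhR null and -0.38 (SE 0.37, adjusted p = 0.87) in AhR-d against control; with 1 array left out these ran from -0.66 to -0.18 and from -0.61 to -0.10.

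AhR null was compared with control to find transcripts that depend on the receptor. Genes of the AhR battery fell in AhR null cells. Ahrr, the AhR repressor and a direct AhR target, stood at 9.07 ± 0.12 in control and was not detected on any AhR null array, which makes it at least 10.3-fold lower (adjusted p = 1.41e-06). Aldh3a1, an aldehyde dehydrogenase, fell by 2.79 (SE 0.36, adjusted p = 0.000184) and Nqo1, a quinone reductase detected on 2 of 3 AhR null arrays, fell by 1.87 (SE 0.29, adjusted p = 0.000765). Cyp1b1, a xenobiotic-metabolising monooxygenase, was at least 2.45-fold lower (adjusted p = 0.00405), and Tiparp, an AhR-induced ADP-ribosyltransferase also detected on 2 of 3 AhR null arrays, fell by 1.16 (SE 0.30, adjusted p = 0.0229). Nfkbia, an inhibitor of NF-κB on the same list, rose by 2.08 (SE 0.31, adjusted p = 0.000632), with detection on 2 of 3 control arrays. Of 11 measured members, 5 fell, 1 rose and 5 did not pass; adjusted over the list alone, 6 fell and 1 rose. The list was called lower (camera adjusted p = 0.0165, median -0.63; -0.45, -0.66 and -0.80 in batches 1 to 3), with adjusted p = 0.168 with an estimated correlation. Tiparp lost its call in the deposited log2 values (-0.23, adjusted p = 0.302) and without any 1 of the AhR null arrays, control replicate 1 or control replicate 3 (adjusted p from 0.0612 to 0.083). The list lost its call with the neutrophil covariate (adjusted p = 0.0785).

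**Figure D1:**
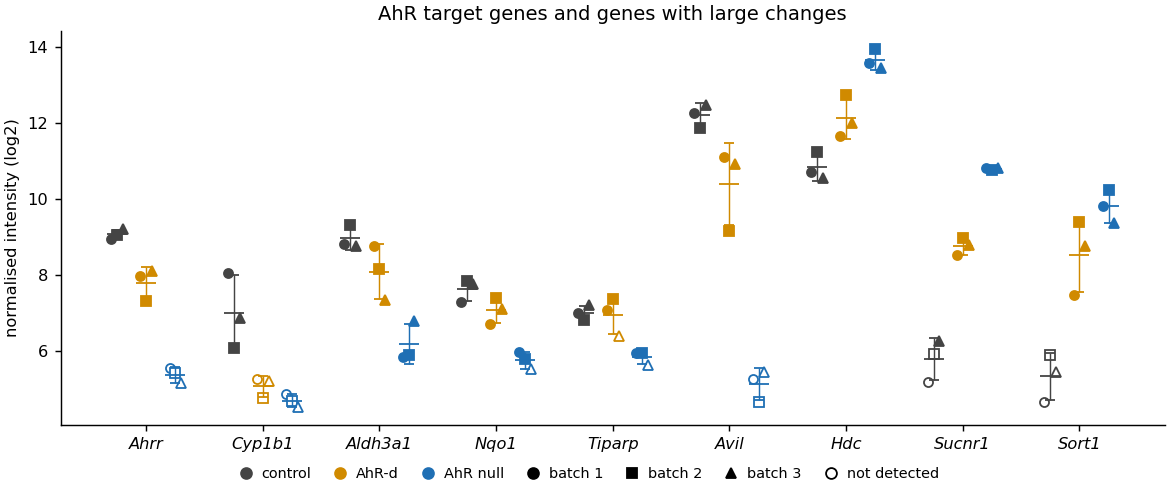
Normalised intensity (log2, vertical axis) of 9 genes on each array, coloured by genotype and shaped by batch; horizontal marks and bars give mean ± SD of 3 arrays, and open symbols are arrays on which the probe was not detected. Ahrr stands at 9.07 in control, 7.80 in AhR-d and, undetected, 5.37 in AhR null, while Sucnr1 stands at 5.79, 8.76 and 10.79.

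Beyond the battery, falls in AhR null were at least 90.3-fold for Avil, which encodes the actin-binding protein advillin (12.20 ± 0.32 in control, not detected on any AhR null array, adjusted p = 1.64e-07), and at least 33.8-fold for Asphd2 (adjusted p = 1.38e-07). Hic1, a transcriptional repressor, Cd96, an immune receptor, and Nxpe4 were also undetected in AhR null, at least 13.6-fold, 10.6-fold and 9.79-fold lower. Hgfac fell by 4.90 (SE 0.27), Mrvi1 fell by 4.23 (SE 0.88), Slco2b1, an organic anion transporter, fell by 4.12 (SE 0.42) and Spns3 fell by 3.98 (SE 0.29), with adjusted p from 1.5e-07 to 0.00652; of these only Mrvi1 was missed on an AhR null array, with detection on 2 of 3. In the other direction, Sucnr1, the succinate receptor, rose by 5.00 (SE 0.26, adjusted p = 1.38e-07), from 5.79 ± 0.55 to 10.79 ± 0.03, with detection on 1 of 3 control arrays. Sort1, which encodes the sorting receptor sortilin, was at least 13.3-fold higher (adjusted p = 2.18e-05), and Greb1 at least 6.66-fold higher (adjusted p = 9.49e-06). Greb1 lies within 20 megabases of Ahr, as does Nfkbia. Hsd11b1, which regenerates active glucocorticoid, rose by 3.88 (SE 0.32, adjusted p = 5.14e-06), and Spink4 rose by 3.64 (SE 0.49, adjusted p = 0.000276), each detected on 2 of 3 control arrays. Mrvi1 lost its call with robust variance settings (adjusted p = 0.0869) and with the brightness covariate (adjusted p = 0.132).

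In total 921 of 7445 features passed the threshold in AhR null against control, 489 higher and 432 lower, and 920 of them differed with 1 sign in all 3 batches. At least a 2-fold change was seen for 323 higher and 237 lower features. With batch as a block, 1580 features passed, 803 higher and 777 lower. The split by direction depended on scaling: the deposited median-centred values gave 824 higher and 90 lower, and median scaling after background correction 837 higher and 86 lower. Of these calls, 565 and 564 were among the 921. Those scalings shifted the median of all genes by 0.29 and 0.53 log2 units, against -0.03 after quantile normalisation, and changes here are relative to the latter. Other scalings gave a more even split. Quantile normalisation with no background correction gave 496 higher and 422 lower, scaling on detected probes 427 and 490, and cyclic loess 515 and 433. The count was 518 without AhR null replicate 1, 500 without AhR null replicate 2, 541 without control replicate 1 and 317 with array brightness as a covariate.

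The mast cell programme did not move one way. Of 23 measured identity genes, 3 rose, 4 fell and 16 did not pass (camera adjusted p = 0.977). Hdc, the enzyme that makes histamine, rose by 2.82 (SE 0.25, adjusted p = 9.53e-06), the amine transporter Slc18a2 rose by 0.75 (SE 0.13, adjusted p = 0.00196), and Mrgprb1, a receptor of the Mas-related family, was at least 5.76-fold higher (adjusted p = 8.19e-05). Csf2rb2, a subunit of the IL-3 receptor, fell by 0.92 (SE 0.16, adjusted p = 0.00183), and Tph1, the serotonin-synthesising hydroxylase, fell by 0.97 (SE 0.24, adjusted p = 0.0165). In the deposited values Csf2rb2 (-0.60, adjusted p = 0.154) and Tph1 (adjusted p = 0.339) lost their calls, and Tph1 did so without AhR null replicate 1 (0.0557), AhR null replicate 2 (0.0781) or control replicate 1 (0.0879). Fcer1a, the IgE-binding chain of the IgE receptor, stood at 14.99 ± 0.21 against 14.85 ± 0.30, a difference of 0.14 (SE 0.16, adjusted p = 0.622). These values lie near the top of the scale, so a change in Fcer1a may have been missed. Among 11 protease genes, 2 rose, 1 fell and 8 did not pass (camera adjusted p = 0.772). Mcpt4, a chymase, rose by 3.33 (SE 0.94, adjusted p = 0.0335) with an SD of 2.80 among AhR null arrays and detection on 2 of 3 control arrays; the difference was 1.80 without AhR null replicate 3. Tpsab1, a tryptase, rose by 2.08 (SE 0.51, adjusted p = 0.0172), or by 1.31 without control replicate 3. Ctsg, which encodes cathepsin G, fell by 1.77 (SE 0.54, adjusted p = 0.047), with detection on 2 of 3 AhR null arrays. Mcpt4 lost its call without AhR null replicate 1 or 3 or any 1 control array (adjusted p from 0.0504 to 0.0943), Ctsg without AhR null replicate 1 or 2 or any 1 control array (0.0822 to 0.186), and Tpsab1 without AhR null replicate 1 (0.0618). With robust variance settings Mcpt4 (0.176) and Tpsab1 (0.0979) lost their calls too.

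Cytokine genes, 18 of them measured, held 2 that rose and 4 that fell (camera adjusted p = 0.812). The chemokine genes moved apart: Ccl4 fell by 2.20 (SE 0.27, adjusted p = 0.000138) and Ccl7 rose by 2.02 (SE 0.33, adjusted p = 0.00121). Osm, which encodes oncostatin M, fell by 1.31 (SE 0.21, adjusted p = 0.0012), and Tnfsf14 fell by 1.51 (SE 0.29, adjusted p = 0.0037); in the deposited values Osm (adjusted p = 0.0518) and Tnfsf14 (0.127) lost their calls. Of 34 antioxidant genes, 8 rose and 1 fell, without a call for the list (camera adjusted p = 0.227). Gpx3 rose by 2.26 (SE 0.41) and Gpx1 by 1.09 (SE 0.21), both glutathione peroxidases, and superoxide dismutase Sod1 rose by 0.90 (SE 0.18), with adjusted p from 0.00293 to 0.00508; Gpx3 was detected on 1 of 3 control arrays. Gpx1 (0.79, adjusted p = 0.0869) and Sod1 (0.57, adjusted p = 0.104) lost their calls with the brightness covariate. S100a8, a myeloid marker, was detected on the 3 AhR null arrays and on 0 control arrays. Hmox1, haem oxygenase, differed by 0.09 (SE 0.44, adjusted p = 0.922), with detection on 2 of 3 arrays in each group. With 1 array left out, its difference ran from -0.51 to 0.43. Among 70 respiratory chain subunits, 2 rose and 0 fell, with 1 rise adjusted over the list alone (median 0.0048, camera adjusted p = 0.771).

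Myeloid transcripts were higher in AhR null cultures. S100a8, a calcium-binding protein abundant in neutrophils and monocytes, was not detected on any control array (4.65 ± 0.15) and stood at 9.54 ± 0.44 in AhR null, at least 10.9-fold higher (adjusted p = 0.0207). Chil3, a secreted lectin of myeloid cells, was at least 4.70-fold higher (adjusted p = 0.031) and Prtn3, a granule protease, at least 1.60-fold higher (adjusted p = 0.0264). Of 8 measured neutrophil markers 3 rose and 5 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0182, median 1.65; 1.60, 1.71 and 1.64 in batches 1 to 3). Its adjusted p = 0.872 with an estimated correlation. Among 9 monocyte and macrophage markers, 5 rose and 1 fell (camera adjusted p = 0.0299, adjusted p = 0.872 with an estimated correlation, median 2.22; 1.49, 2.34 and 2.11 in batches 1 to 3). Apoe, a lipid carrier detected on 1 of 3 control arrays, rose by 3.69 (SE 0.48, adjusted p = 0.000203), and Cx3cr1, a chemokine receptor, fell by 1.60 (SE 0.35, adjusted p = 0.00814). The single-gene neutrophil calls were near the threshold in the fit of all 3 genotypes: Chil3 lost its call without any 1 of the 6 arrays (adjusted p from 0.0588 to 0.0903), and S100a8 (0.0504 to 0.0712) and Prtn3 (0.0562 to 0.0998) without any of them but control replicate 2. The fitted differences, against undetected controls, moved little in those runs (S100a8 from 4.70 to 5.07, Chil3 from 3.26 to 3.82, Prtn3 from 1.67 to 2.05). The SD of S100a8 was 3.93 in AhR-d, which shares the fit and so adds to its SE of 1.25, and all 3 genes kept their calls with lower adjusted p-values when only the 2 groups were fitted; with robust variance settings S100a8 (0.144) and Chil3 (0.157) lost their calls. The neutrophil list lost its call without control replicate 1 (adjusted p = 0.0533), and the monocyte list without AhR null replicate 3 (0.131) or control replicate 1 (0.104), while Cx3cr1 lost its call in the deposited values (0.0755).

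Markers of megakaryocytes and red cells, 11 measured, held 4 that rose and 1 that fell (camera adjusted p = 0.0182, adjusted p = 0.168 with an estimated correlation, median 0.92; 1.06, 1.00 and 0.66 in batches 1 to 3). The erythroid transcription factor gene Klf1 was at least 1.80-fold higher (adjusted p = 0.00985), and Vwf, which encodes von Willebrand factor, fell by 3.04 (SE 0.55, adjusted p = 0.0029). Outside that list, the beta-globin genes Hbb-y and Hbb-bt rose by 4.37 (SE 0.65) and 3.95 (SE 0.71), at adjusted p = 0.000613 and 0.0025, with detection on 1 and 2 of 3 control arrays. Progenitor markers fell: 3 of 8 were lower, 0 higher and 5 did not pass (camera adjusted p = 0.0165, adjusted p = 0.168 with an estimated correlation, median -0.64; -0.58, -0.67 and -0.70 in batches 1 to 3). Runx1, a haematopoietic transcription factor, fell by 1.30 (SE 0.22, adjusted p = 0.00193) and Cd34, a surface sialomucin of progenitors, fell by 0.93 (SE 0.24, adjusted p = 0.0237). In the deposited values the progenitor list (adjusted p = 0.0525), Runx1 (0.237) and Cd34 (0.501) lost their calls, and Cd34 did so without AhR null replicate 1 (0.11), AhR null replicate 3 (0.0874), control replicate 1 (0.0649) or control replicate 2 (0.0744). The megakaryocyte and red cell list lost its call without AhR null replicate 2 (0.0592), and Klf1 without AhR null replicate 1 (0.0513) or 2 (0.0638).

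**Figure D2:**
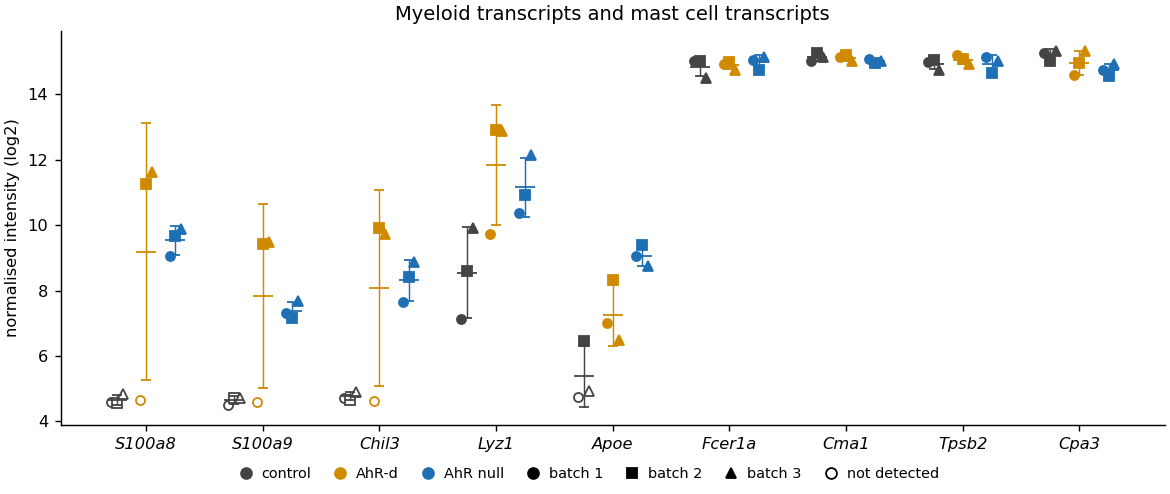
Normalised intensity (log2, vertical axis) of 5 myeloid and 4 mast cell transcripts on each array, coloured by genotype and shaped by batch; horizontal marks and bars give mean ± SD of 3 arrays, and open symbols mark arrays without detection. S100a8 is undetected in the 3 controls and in AhR-d replicate 1, stands at 11.3 and 11.6 on the other AhR-d arrays and at 9.54 on average in AhR null, and Fcer1a lies near 15, close to the top of the scale, on all 9 arrays.

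AhR-d was compared with control to see which transcripts differ with the altered allele. Sort1 was at least 5.47-fold higher (adjusted p = 0.00549), and Sucnr1, detected on 1 of 3 control arrays, rose by 2.97 (SE 0.26, adjusted p = 0.000144). Retnla, a secreted protein induced by IL-4 in macrophages and detected on 1 of 3 control arrays, rose by 2.87 (SE 0.55, adjusted p = 0.0453), Hsd11b1 by 2.73 (SE 0.32, adjusted p = 0.00154) and Ccl7 by 1.98 (SE 0.33, adjusted p = 0.02). Nrp1, a semaphorin co-receptor, rose by 1.95 (SE 0.30, adjusted p = 0.0139), Ramp1 by 1.86 (SE 0.34, adjusted p = 0.0449) and Hdc by 1.30 (SE 0.25, adjusted p = 0.0462). Among controls, Hsd11b1 and Nrp1 were detected on 2 of 3 arrays and Ramp1 on 1. Insyn1, Aard and Zfp326 were at least 2.96-fold, 2.14-fold and 2.01-fold higher, with detection on 0 of 3 control arrays. The named genes that fell were Zfp277, by 1.92 on the log2 scale (-1.92, SE 0.20, adjusted p = 0.000787), Asphd2 (-1.67, SE 0.31), Myadm (-0.87, SE 0.16) and Erdr1, undetected in AhR-d and at least 2.47-fold lower. The last 3 each had adjusted p = 0.0449.

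In total 25 features passed in AhR-d against control, 21 higher and 4 lower, each with 1 sign in all 3 batches; 561 had an unadjusted p under 0.05. With batch as a block 118 passed, 87 higher and 31 lower. The deposited values gave 9, all higher, and median scaling gave 41, with 38 higher and 3 lower. Of these calls, 6 and 16 were among the 25. The count was 46 without AhR-d replicate 1, 5 without AhR-d replicate 2 and 7 without control replicate 1. With the neutrophil covariate, which itself differed between the groups, the count was 1, the call of Sucnr1. Without AhR-d replicate 2, the calls of Retnla (adjusted p = 0.262), Ccl7 (0.11), Nrp1 (0.106), Ramp1 (0.233), Hdc (0.233), Insyn1 (0.233), Aard (0.11), Zfp326 (0.0803), Asphd2 (0.233), Myadm (0.22) and Erdr1 (0.156) were lost, while Sucnr1, Sort1, Hsd11b1 and Zfp277 kept theirs without any 1 of the 6 arrays. The lost genes other than Zfp326 were also lost without control replicate 1 (0.081 to 0.272), and Zfp277 lost its call in the deposited values (0.173). The myeloid marker S100a8 was detected on AhR-d replicates 2 and 3 and on 0 control arrays.

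None of 5 AhR targets passed the threshold in AhR-d. Ahrr differed from control by -1.28 (SE 0.26, adjusted p = 0.0596), Aldh3a1 by -0.88 (SE 0.36, adjusted p = 0.539; -0.50 without AhR-d replicate 3), Nqo1 by -0.55 (SE 0.29, adjusted p = 0.716) and Tiparp by -0.06 (SE 0.30, adjusted p = 0.992; -0.26 to 0.22 with 1 array left out). Cyp1b1 was undetected in AhR-d (at least 1.96-fold lower, adjusted p = 0.103). With batch as a block, Ahrr and Cyp1b1 passed the threshold. The AhR battery was called lower as a list with 0 of 11 members past the threshold (camera adjusted p = 0.0189, adjusted p = 0.212 with an estimated correlation, median -0.38; -0.13, -0.15 and -0.80 in batches 1 to 3), and 2 members fell adjusted over the list alone. That call was lost without AhR-d replicate 3 (adjusted p = 0.131), without control replicate 3 (0.0604) and with the neutrophil covariate (0.302).

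Myeloid lists were higher in AhR-d too, the neutrophil list on replicates 2 and 3 and the monocyte list in all 3 batches. None of the 8 neutrophil markers passed over all genes, 6 rose adjusted over the list alone, and the list was called higher (camera adjusted p = 9.33e-08, adjusted p = 0.274 with an estimated correlation); its median was 1.59 overall and 0.11, 2.58 and 2.32 in batches 1 to 3. S100a8 stood at 9.18 ± 3.93, with detection on 2 of 3 AhR-d arrays. Monocyte and macrophage markers were called higher with 0 of 9 past the threshold and 4 adjusted over the list alone (camera adjusted p = 7.43e-06, adjusted p = 0.212 with an estimated correlation, median 1.17; 0.83, 1.98 and 1.55 in batches 1 to 3). Lyz2, a lysozyme of myeloid cells detected on 2 of 3 control arrays, differed by 3.83 (SE 0.90, adjusted p = 0.115), and by 3.74 in batch 1. With batch as a block, Lyz2 (adjusted p = 0.000144), Lyz1 (4.54e-05), Apoe (0.00227), S100a8 (0.0194), Chil3 (0.0256) and S100a9 (0.0346) passed the threshold. Markers of megakaryocytes and red cells were called higher with 0 of 11 members past the threshold (camera adjusted p = 0.0254, adjusted p = 0.212 with an estimated correlation, median 0.49; 0.20, 0.93 and 0.06 in batches 1 to 3). That call was lost without AhR-d replicate 2 (adjusted p = 0.242), control replicate 1 (0.0728) or control replicate 2 (0.0778), and it and the monocyte call with the neutrophil covariate (0.572 for both).

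Cell cycle genes, 35 measured, were called higher in AhR-d than in control with 0 past the threshold (camera adjusted p = 0.000811, adjusted p = 0.274 with an estimated correlation, median 0.31; 0.11, 0.31 and 0.50 in batches 1 to 3). Ube2c, a ubiquitin-conjugating enzyme of mitosis, differed by 1.03 (SE 0.32, adjusted p = 0.294) and Rrm2, a ribonucleotide reductase subunit, by 0.84 (SE 0.28, adjusted p = 0.335). The call was lost without AhR-d replicate 3 (adjusted p = 0.17), without control replicate 2 (0.0771) and with the neutrophil covariate (0.257); the myeloid marker S100a8 was detected on AhR-d replicates 2 and 3 and on 0 control arrays. Glycolysis genes, 19 measured and 0 past the threshold, were called lower (camera adjusted p = 0.0457, adjusted p = 0.274 with an estimated correlation, median -0.17; -0.02, -0.52 and -0.11 in batches 1 to 3), with hexokinase gene Hk2 at -0.57 (SE 0.18, adjusted p = 0.294). Adjusted over the list alone 0 members fell and 1 rose, the glucose transporter gene Slc2a1 (0.77, SE 0.19, adjusted p = 0.134 over all genes). That call was lost without AhR-d replicate 2 (adjusted p = 0.177), AhR-d replicate 3 (0.205), control replicate 1 (0.0665) or control replicate 2 (0.442), or in the deposited values (0.13) and with the neutrophil covariate (0.602). The glycolysis call also depended on counting the list chosen by the study in the adjustment: over the fixed lists alone it would not pass.

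The direct comparison of AhR null with AhR-d tested where the 2 altered genotypes differ. Avil was undetected in AhR null and at least 25.8-fold lower than in AhR-d (adjusted p = 8.17e-06), and Ahrr at least 4.26-fold lower (adjusted p = 0.000245). Asphd2 and Hic1 were at least 10.7-fold and 7.76-fold lower, and Spns3 and Hgfac fell by 3.62 (SE 0.29) and 3.53 (SE 0.27), with adjusted p from 8.17e-06 to 9.72e-05. Retnla and Il1r2, which encodes a decoy receptor for IL-1, were undetected in AhR null, at least 8.47-fold (adjusted p = 0.00443) and 3.78-fold lower (adjusted p = 0.00244). Higher in AhR null were Greb1 by 2.81 (SE 0.35, adjusted p = 0.00086), Scara5, a scavenger receptor, by 2.44 (SE 0.41, adjusted p = 0.00494), Sucnr1 by 2.03 (SE 0.26, adjusted p = 0.000955) and Hdc by 1.52 (SE 0.25, adjusted p = 0.00494); Greb1 was detected on 2 of 3 AhR-d arrays and Scara5 on 1. The AhR battery held 3 members that fell and 1 that rose, without a call (camera adjusted p = 0.0661). Aldh3a1 fell by 1.91 (SE 0.36, adjusted p = 0.0107), and Nqo1 by 1.32 (SE 0.29, adjusted p = 0.0263), but in the deposited values neither passed (adjusted p = 0.141 and 0.247). Nqo1 lost its call without any 1 of the 6 arrays but AhR-d replicate 1 (adjusted p from 0.0712 to 0.102), and Aldh3a1 without AhR null replicate 1 (0.0676) or 2 (0.0559).

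Cell cycle genes were lower in AhR null than in AhR-d: 2 of 35 fell, 0 rose and 33 did not pass, with 7 lower adjusted over the list alone (camera adjusted p = 1.11e-05, adjusted p = 0.246 with an estimated correlation, median -0.55; -0.25, -0.32 and -0.82 in batches 1 to 3). Tpx2, a spindle assembly factor, fell by 1.38 (SE 0.33, adjusted p = 0.0399) and the replication licensing gene Mcm6 fell by 0.74 (SE 0.15, adjusted p = 0.0187); neither passed in the deposited values (adjusted p = 0.205 and 0.613), nor without AhR-d replicate 3 (0.192 and 0.0687) or any 1 AhR null array (0.062 to 0.166 and 0.0558 to 0.0819). Tpx2 also lost its call without AhR-d replicate 2 (0.0698), and Mcm6 without AhR-d replicate 1 (0.0505). Progenitor markers were called lower, with 1 of 8 past the threshold (camera adjusted p = 0.0222, adjusted p = 0.246 with an estimated correlation, median -0.38; -0.41, -0.36 and -0.59 in batches 1 to 3), a call lost in the deposited values (adjusted p = 0.111). Runx1 fell by 0.97 (SE 0.22, adjusted p = 0.0361), a call lost without any 1 of the 6 arrays (adjusted p from 0.0602 to 0.159). The neutrophil (camera adjusted p = 0.608) and monocyte lists (0.943) were not called.

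In total 185 features passed in AhR null against AhR-d, 61 higher and 124 lower, each with 1 sign in all 3 batches. With batch as a block 502 passed, 218 higher and 284 lower. The balance depended on scaling: the deposited values gave 138 higher and 26 lower and median scaling 88 higher and 36 lower, with the median of all genes shifted by 0.24 and 0.38 log2 units. Of these calls, 79 and 82 were among the 185. Quantile normalisation without background correction gave 83 higher and 98 lower, scaling on detected probes 58 and 128, and cyclic loess 78 and 132. The count was 84 without AhR-d replicate 3, 82 without AhR null replicate 1, 84 without AhR null replicate 2 and 101 with the brightness covariate.

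The effects of both genotypes against control ran in the same direction for most genes called in AhR null. Of the 921 features called there, 885 had the same sign in AhR-d (96.1%). In simulations that shared the control arrays, kept the AhR null effects and left AhR-d unchanged, 64.1% did (highest of 100 simulations, 67.6%). The effects kept were the estimated ones, which already hold noise of the real control arrays, so this simulated share may be too low. Across all 7445 features, which are not independent replicates, the effects correlated at Pearson's r = 0.72 and Spearman's rho = 0.65, against 0.50 and 0.47 in simulations with both groups unchanged. Their covariance was 0.198, against a simulated 0.0425. Simulated noise was independent between genes and arrays, so genes that move together and batches shared by arrays are left out of these simulated values. Of the 21 features called higher in AhR-d, 20 were called higher in AhR null, where independent lists would share 1.38; of the 4 called lower, 2 were shared, against 0.232. With 3 control arrays, splitting the controls was not possible with at least 2 per part, so part of the overlap above that of independent lists may come from the shared controls.

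**Figure D3:**
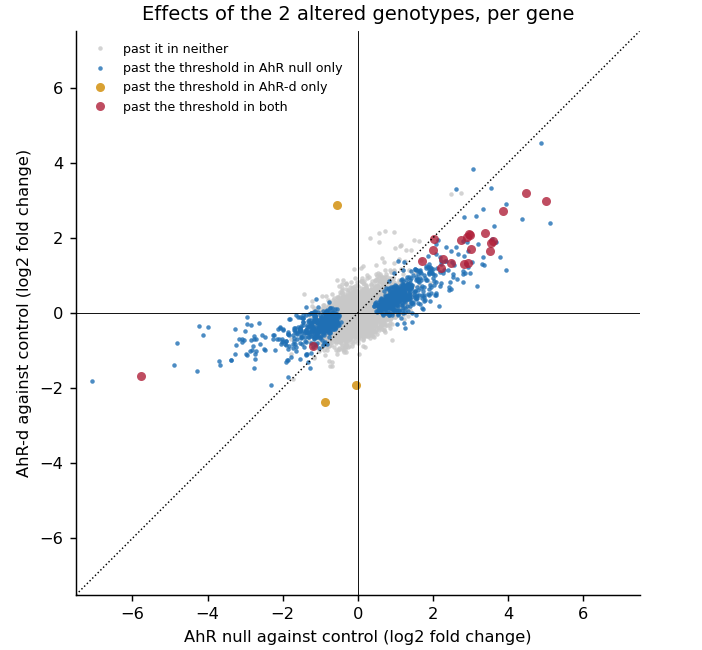
Log2 fold change of AhR-d against control (vertical axis) plotted on that of AhR null against control (horizontal axis), 1 point per tested feature, coloured by the comparison in which it passed the threshold; the dotted line marks equal effects. Of the 921 features called in AhR null, 885 lie on the same side of zero in both comparisons.

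The 45 probes the study deposited separately, among them mitochondrial genes, were tested as a list the study chose on these samples, so the list is not independent evidence of its direction. In AhR null against control 18 probes rose and 0 fell, with a median of 0.56 in normalised values. In the deposited values the median was 0.78, beside 0.29 for all probes. The list test used each gene's brightest probe, which for some genes is not the deposited one: 16 of 43 features rose (camera adjusted p = 4.92e-10, adjusted p = 0.0213 with an estimated correlation), and 17 rose and 1 fell adjusted over the list alone. The latter was Mrps11, chosen after its values were seen, at -0.63 on its brightest probe and 0.89 on the deposited one. Ppif, the mitochondrial cyclophilin, rose by 1.40 (SE 0.20, adjusted p = 0.000515) and Fis1, a mitochondrial fission factor, rose by 0.56 (SE 0.16, adjusted p = 0.0353), a call lost in the deposited values (adjusted p = 0.0581) and without any 1 of the 6 arrays but control replicate 2 (0.0589 to 0.12). Transglutaminase gene Tgm2 rose by 2.67 (SE 0.34, adjusted p = 0.000165). In AhR-d against control, 0 of the 45 deposited probes passed (median 0.28), and on the brightest probes 1 of the 43 features, Rab11fip5, rose by 1.43, against 0.83 on its deposited probe. The list there had camera adjusted p = 1.27e-05 (adjusted p = 0.114 with an estimated correlation). In AhR null against AhR-d, 2 of the 45 deposited probes and 2 of 43 features rose (camera adjusted p = 2.19e-07, adjusted p = 0.0473 with an estimated correlation).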

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

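The tests on myeloid transcripts, dilution, array brightness, the window around Ahr and the second Zfp277 probe were chosen after the result was seen; the counts over other splits of the arrays and the test of the rest of chromosome 12 were set before.

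Of the genes called in AhR-d against control, 2 had an AhR-d difference that was larger in size than the AhR null difference and a direct test between the genotypes that passed. Zfp277 fell in AhR-d (6.73 ± 0.09 against 8.64 ± 0.16 in control) and stood at 8.59 ± 0.04 in AhR null, so AhR null exceeded AhR-d by 1.86 log2 units (adjusted p = 0.000247). Retnla was higher in AhR-d (8.79 ± 1.03) than in control (5.92 ± 1.19, detected on 1 of 3 arrays). It was undetected in AhR null (5.37 ± 0.21), at least 8.47-fold lower there than in AhR-d (adjusted p = 0.00443). The fitted AhR null minus AhR-d value of -3.42 lies against background and is no measured fold. On AhR-d replicates 1 to 3 Retnla stood at 7.63, 9.58 and 9.16, and the myeloid marker S100a8 was undetected on replicate 1 and at 11.3 and 11.6 on the others. In AhR null, where Retnla was undetected, S100a8 was detected on 3 of 3 arrays. The Retnla call against control was lost without AhR-d replicate 2, as given above. Whether myeloid cells carry its signal was not tested.

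Zfp277 lies within 20 megabases of Ahr on chromosome 12, where 8 of 57 measured genes were called in AhR null against AhR-d, against 177 of 7388 elsewhere (two-sided Fisher's exact p = 7.28e-05). DNA of a donor strain that stayed beside the altered alleles may account for this, and 0.549% of 6554 overlapping windows of equal width on other chromosomes held as large a share of called genes. A property of all of chromosome 12 is argued against by the rest of the chromosome, where 1.82% of measured genes were called, against 2.52% on other chromosomes. For AhR null against control the window stood out less, with 11 of 57 genes called (exact p = 0.109) and 6.29% of other windows as high. Zfp277 was among the 8 called in AhR null against AhR-d, as were Greb1 and Nfkbia, which were also among these 11. In AhR-d against control 1 of 57, Zfp277 itself, was called (exact p = 0.175), with 2.40% of other windows as high, values that only restate its call. Whether a strain variant under the Zfp277 probe or a real difference lowers its signal cannot be told apart, since 0 of its 2 other probes was detected on all 3 control arrays; regulation of these neighbours by AhR also stays open and was not tested.

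Neutrophil and monocyte lists were called higher in AhR null and in AhR-d, calls that did not hold with an estimated correlation. In AhR-d the neutrophil list was higher in batches 2 and 3 (medians 2.58 and 2.32) than in batch 1 (0.11), and Lyz1 and Lyz2 were above control in all 3 batches. Carried-over myeloid cells may be a source, and joint regulation of these genes inside the mast cells would give the same test value, so both stay open: the 8 measured neutrophil markers deviated together within genotypes, with a mean pairwise correlation of 0.834, against at most 0.401 in 1000 random lists matched on level, although bead selection was meant to remove such cells and nearly all cells carried mast cell surface markers, per the labels. That correlation pooled all 3 genotypes and says little of AhR null. The SD of S100a8 was 3.93 in AhR-d, where replicate 1 stood at 4.65, 0.44 in AhR null and 0.15 in control, where it was undetected. The monocyte list gave 0.295, with no random lists matched to it. The level of S100a8 reached 11.3 and 11.6 on AhR-d replicates 2 and 3 while Lyz1 reached 12.9 on both, and Lyz1 was also detected on the 3 control arrays (8.54 ± 1.39). Dilution of mast cell RNA as a reason for the genes that fell in AhR null is not settled. A set of 14 abundant mast cell transcripts below the top of the scale had a median of -0.063 (SD 1.04). The 432 fallen genes had a median of -1.07, a gap within that SD. That SD is the spread among the 14 genes, of which 4 fell and 2 rose, and not the error of their median. Another 16 transcripts above a level of 12, some near the top of the scale and some shared with the first set, had a median of 0.038 (SD 0.87). Of these, 2 fell and 2 rose. Neither set showed a common fall of the size seen in the fallen genes.

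In the deposited values most genes called in AhR null were higher, 824 against 90, and after quantile normalisation 489 against 432. Brightness left in by centring arrays on a median that lies in the background and more RNA per cell in AhR null cannot be told apart. Medians over the 6999 probes detected on all arrays differed by 0.422 log2 units between AhR null and control and ranged over 0.369 within control, 0.232 within AhR null and 0.865 within AhR-d, with every AhR null array (lowest 9.68) above every control array (highest 9.60). Mean signal gave an exact two-sided p of 0.2 and the number of probes detected one of 0.1, the smallest possible, and quantile normalisation removes such a difference by construction.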

How the results depend on the processing

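The runs with scaling on detected probes, cyclic loess, the brightness covariate, the neutrophil covariate and without batch 3 were chosen after seeing the data; the others were planned. For AhR null against control (921 features) the count moved by over 1.5 times to 560 with at least a 2-fold change, 1580 with the replicate block, 1424 with batch as a random block, 1487 with array weights and 317 with array brightness as a covariate, of which 302 were among the 921. For AhR-d against control (25) it moved to 118 with the replicate block, 70 with a random block, 55 with array weights, 41 with median scaling, 13 without an intensity trend, 12 without batch 3, 10 with only the 2 groups compared, 9 in the deposited log2 values, 7 without background correction and 1 with the neutrophil covariate. For AhR null against AhR-d (185) it moved to 502 with the replicate block, 370 with a random block, 325 with array weights, 101 with the brightness covariate and 89 without batch 3. Every feature called without the block was also called with it in all 3 comparisons, and the block changed no list call. Array weights were not run for lists, and a list by position within 20 megabases of Ahr was run beside the named neighbours. Leaving out 1 array at a time gave 500 to 880, 5 to 46 and 82 to 216 features in those comparisons. Fewer arrays or a larger minimum fold explain part of these moves by construction; for the rest the cause was not tested.

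With an estimated correlation, 0 of the 5, 6 and 2 called lists stayed called, counts that leave out the list chosen by the study. That list kept its call in AhR null against control and in AhR null against AhR-d. Of the 6, the glycolysis call depended on counting that list in the adjustment. In AhR null against control, fry passed the AhR battery (adjusted p = 0.000276), progenitor (0.00469), megakaryocyte (0.0113), calcium (0.0113) and reactive oxygen lists (0.0285). The neutrophil (0.344) and monocyte lists (0.159) did not pass. In AhR-d against control, the AhR battery alone of the fixed lists passed fry (0.0379). In AhR null against AhR-d, fry passed the AhR battery (0.00494) and the cell cycle (0.0251), reactive oxygen (0.00494) and calcium lists (0.00658). The number of lists called by camera in AhR null against control moved to 2 without a filter, 3 with cyclic loess, 3 without batch 3 and 1 with the neutrophil covariate. In AhR-d against control it moved to 0 with the neutrophil covariate, under which the neutrophil list turned direction (adjusted p = 0.961); that covariate is the list's own mean. In AhR null against AhR-d it moved to 1 without a filter and 4 with scaling on detected probes. Leaving out 1 array gave 3 to 5, 3 to 9 and 2 to 4 called lists, and a correlation of the genotype effects from 0.59 (without AhR-d replicate 1) to 0.78 (without control replicate 2). Over named genes, 5148 values stayed on the same side of the threshold, 655 lost the threshold and 152 gained it. Reversals were 0 among values past the threshold in either fit. Values past it in neither could change sign, as Hmox1 did in AhR null against control (-0.51 to 0.43 with 1 array left out). Signal over background set a limit: 132 of the 921 features were undetected on every array of 1 group, so their differences are bounds.

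Other splits of each set of 6 arrays into 3 and 3 numbered too few, 10 with the real one, for a share under 0.05. As many features were called in 1 split, the real one, in each comparison. The highest other split gave 0 against 921, 1 against 25 and 2 against 185 features. Among the 4 splits that part all 3 batch pairs, the other splits gave 0 in each comparison. Other splits mix the genotypes in each part, so differences between genotypes enter the residual spread. Low counts there follow at least in part by construction, and no conclusion is drawn from them.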

Other observations

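The tests in this part were chosen before the data were examined, as gene lists or named genes, except where a gene is marked.

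Several gene groups held members that moved apart in AhR null against control. Of 33 genes of IgE receptor and Kit signalling, 4 rose and 2 fell (camera adjusted p = 0.771): the phosphatase gene Dusp2 rose by 2.61 (SE 0.53, adjusted p = 0.00577), while the adaptor gene Lat fell by 0.80 (SE 0.20, adjusted p = 0.0173), a call lost in the deposited values (0.576) and without AhR null replicate 2 (0.0825), control replicate 1 (0.0811) or control replicate 2 (0.0537). Of 29 calcium and exocytosis genes, 3 rose and 1 fell (camera adjusted p = 0.671); the potassium channel gene Kcnn4 fell by 2.07 (SE 0.23, adjusted p = 5.57e-05) and the SNARE gene Snap23 rose by 0.76 (SE 0.16, adjusted p = 0.00801). Among 21 interferon-stimulated genes, 5 rose and 1 fell (camera adjusted p = 0.295): Usp18 fell by 1.98 (SE 0.22, adjusted p = 5.89e-05), while Ifi47 rose by 1.68 (SE 0.21, adjusted p = 0.000133). Of 7 genes for producers of reactive oxygen, the NADPH oxidase gene Ncf4 fell by 2.77 (SE 0.22, adjusted p = 5.14e-06) and the small GTPase gene Rac2 rose by 1.24 (SE 0.24, adjusted p = 0.00423; list camera adjusted p = 0.977). Of 27 other mitochondrial genes, 5 rose and 0 fell (camera adjusted p = 0.771), among them Vdac3, an outer membrane channel (1.27, SE 0.23, adjusted p = 0.00288).

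Of 7 basophil markers, 1 rose and 1 fell in AhR null against control (camera adjusted p = 0.779). Prss34, a protease of basophils that immature mast cells also make, rose by 2.94 (SE 0.52, adjusted p = 0.00239), the interferon-induced gene Ifitm1 fell by 2.96 (SE 0.19, adjusted p = 5.47e-07), and Mcpt8, chosen after its values were seen, stood at 9.03 ± 0.71 in AhR null and 8.55 ± 0.43 in control. Of 7 dendritic cell and antigen presentation markers, 0 rose and 0 fell (camera adjusted p = 0.771). Genes fixed in advance as neighbours of Ahr, 18 measured, held 1 that rose and 3 that fell (camera adjusted p = 0.977). The remaining lists were not called in AhR null against control: eicosanoids (0 rose and 1 fell of 11, camera adjusted p = 0.977), unfolded protein response (0 and 1 of 27, 0.898), apoptosis (1 and 1 of 26, 0.812), cell cycle (0 and 3 of 35, 0.469), glycolysis (1 and 3 of 19, 0.611), cholesterol synthesis (3 and 2 of 18, 0.812), ribosomal proteins (4 and 1 of 53, 0.904), tryptophan and serotonin (1 and 1 of 7, 0.863), TGF-beta and adhesion (4 and 3 of 21, 0.977) and early response genes (1 and 1 of 20, 0.771). Among those called in the window of 20 megabases were Id2 (-1.55, adjusted p = 0.000111) and Adi1 (1.75, adjusted p = 0.00122), both chosen after their values were seen. Greb1 and Nfkbia, given above, were also called there.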
